A study of Rattus norvegicus with 23 samples.

How the data were processed

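Gene expression was measured by RNA sequencing in hearts and kidneys of Sprague-Dawley rats aged 13 weeks, collected 4 weeks after surgery. The rats had sham surgery (Sham), partial removal of kidney tissue (NX, a standard way of producing chronic kidney disease) or the same nephrectomy together with a surgical connection between the carotid artery and the jugular vein (AVF+NX, the kind of arteriovenous fistula made as an access for dialysis). The 23 libraries came from 4 samples per organ and group, except for heart Sham with 3. RNA was poly(A)-selected and the libraries were strand-specific, per the labels' protocols. The labels number the replicates as biological replicates and do not say which heart and kidney came from the same rat.

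The deposited files hold whole-number read counts per gene with chromosome, start, end, strand and length columns, as featureCounts writes them, per the file headers. Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2 are named in the submitters' processing notes without a role or order. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Values of genes that overlap another gene on either strand are therefore uncertain, and coordinates are printed as the files give them. The authors also deposited, for each of the 6 comparisons within an organ, a table of log2 fold changes with p-values and adjusted p-values. The tool and the adjustment behind the authors' p-values are not given in the sources used here. The same deposited tables hold a normalised signal per library, which was checked to equal the library's count divided by 1 factor per library and table. Those tables list genes whose counts, summed over the libraries compared, exceeded 10 per library (checked on the files). Values printed here come from the counts, and the authors' calls are named as theirs.

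Gene symbols were taken from the authors' tables, which pair 15123 of the 32552 gene identifiers with a symbol. The reference table of gene names added 0. Among the genes tested, 18 carry a symbol that has been turned into a date in those tables, and they are not named here. Total counts per library ran from 9069354 to 48079431. Genes tested held 99.9% of the counts in the heart library with the lowest share and 99.8% in the kidney library with the lowest share. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 6.49, so none was treated as a repeated library.

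Each organ was fitted once with its 3 groups in edgeR 4.0.16 (R 4.3.3). Genes passing filterByExpr were kept (12794 in heart, 14322 in kidney), libraries were scaled by TMM, and dispersions and quasi-likelihood fits were robust. The quasi-likelihood F test gave p-values, which were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05. The standard error of a log2 fold change is the fold change divided by the square root of F. The typical biological coefficient of variation was 0.156 in heart and 0.176 in kidney. CPM values (counts scaled to the TMM-adjusted library total) are given as mean ± SD over a group. Differences between the organs were tested as the heart effect minus the kidney effect in 1 fit of all 23 libraries.

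Gene lists for pathways, cell types and possible neighbouring tissues (35 for heart, 39 for kidney) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes. Adjustment was over the lists of a comparison, and lists with at least 5 measured members were tested (30 in heart, 36 in kidney). Camera with a correlation estimated per list and fry were run beside it. Fry asks whether a list's genes move, on balance, 1 way, and does not compare the list with other genes. Counts of members called are given over all genes and adjusted over the list alone.

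Genes were named by a fixed rule. In each comparison these were the 8 called genes with the largest rise and the 8 with the largest fall (mean of at least 1 CPM over the groups compared, with a symbol that is not a placeholder), and up to 4 members with the smallest p of each list called or described. Nppa, Nppb, Myh7, Myh6, Col1a1, Col3a1, Postn and Timp1 were always named in heart, and Havcr1, Lcn2, Spp1, Umod, Slc34a1, Kl and Col1a1 in kidney. With 15 or fewer called genes, all with a symbol were named. For the organ difference the 5 genes with the smallest p in each direction were named. The text prints a part of the genes the rule gives, and counts over called genes of the rule include genes that are not reported here. The groups, the tests, the lists, this rule and the first set of alternatives were chosen before the data were examined.

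The first set of alternatives held size factors of DESeq2 (RLE) for TMM, no count filter, a fold threshold of 2, fits of only the groups compared, the replicate number as a term, DESeq2 1.42.0, limma voom with sample quality weights, and each library left out in turn. Alternatives added later were a covariate of log2 total count, a covariate of small structured RNA, a covariate of clock genes, thinning to equal depth, removal of each library's trend over gene length, and kidney fits without 2 libraries with high urothelial counts. The small RNA index of a library is the median, over 64 genes named after an Rfam family with a mean above 0.5 CPM in heart, of its log2 CPM minus the gene's mean. The clock index is the mean deviation of Arntl, Npas2, Clock and Nfil3 minus that of Per2, Per3, Nr1d1, Nr1d2, Dbp, Tef, Hlf, Ciart and Usp2.

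The gene test was tested on simulated counts with 1 mean per gene over all libraries of a fit and the libraries' own depths. For the organ difference that mean pools heart and kidney. No structure among libraries of a group was simulated, so the shares below hold for counts without it. For heart AVF+NX vs Sham, run on 12655 genes, it recovered 22.4% of the genes changed 1.5-fold, 76.1% of those changed 2-fold and 95.5% of those changed 4-fold, with 5 wrong calls among 134. For kidney AVF+NX vs Sham, run on 14175 genes, the shares were 41.8%, 82.1% and 98.5%, with 7 wrong calls among 155. For the organ difference of NX vs Sham, run on 14591 genes, they were 10.4%, 56.7% and 74.2%. Where p-values come from samples alone, they measure the spread between these rats.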

Results

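Hearts and kidneys were profiled after sham surgery, after partial nephrectomy (NX) and after nephrectomy combined with an arteriovenous fistula (AVF+NX). Each organ gave 4 NX and 4 AVF+NX libraries, with 3 Sham libraries in heart and 4 in kidney. Heart libraries held 9894716 to 11866042 counts after sham surgery, 9605973 to 22679092 after NX and 11889483 to 48079431 after AVF+NX, so depth differed between the heart groups. Kidney libraries held 9069354 to 12637718 counts, except NX library 4 with 18782085. Mitochondrial genes took 21.4% ± 0.76 (SD, n = 3) of the counts in sham hearts, 20.2% ± 1.23 (n = 4) after NX and 23.5% ± 1.75 (n = 4) after AVF+NX. The shares in kidney were 8.55% ± 0.77, 8.15% ± 2.67 and 7.53% ± 1.47 (n = 4 each). At these depths and group sizes a change of 1.5-fold was often missed, with 34.3% of such genes recovered in simulated NX vs Sham heart counts of 12648 genes.

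**Figure D1:**
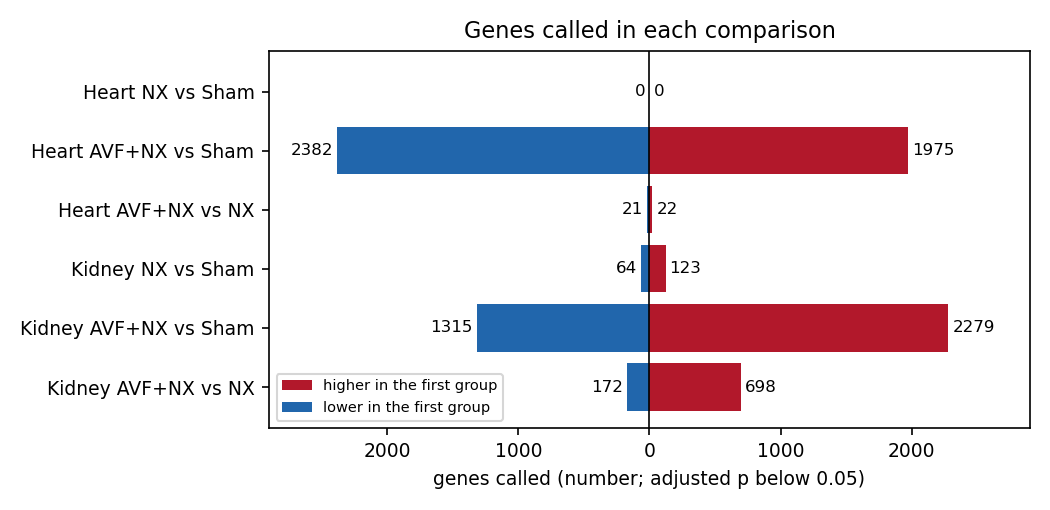
Number of genes called in each comparison (adjusted p below 0.05), with genes higher in the first-named group to the right and lower genes to the left. The AVF+NX vs Sham comparisons gave 1975 higher and 2382 lower genes in heart and 2279 higher and 1315 lower genes in kidney, and NX vs Sham in heart gave 0.

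The first heart comparison asks what nephrectomy alone was followed by in the heart. No gene passed the test. Kdr, a receptor for vascular endothelial growth factor, averaged 210 ± 22.7 CPM (SD, n = 4) after NX and 128 ± 3.39 CPM (n = 3) after sham surgery, a log2 fold change of 0.72 (SE 0.17, adjusted p = 0.141). Lox, which crosslinks collagen, and Lyz2, the lysozyme of macrophages, had log2 fold changes of 0.80 (SE 0.21, adjusted p = 0.146) and 0.76 (SE 0.19, adjusted p = 0.143). The natriuretic peptide genes Nppa and Nppb, which the heart releases when stretched, stood at 0.68 (SE 0.64) and 0.74 (SE 0.36), and the myosin heavy chains Myh6 and Myh7 at 0.07 (SE 0.14) and -0.07 (SE 0.28). Col1a1, Col3a1 and Timp1 had values of 0.46 (SE 0.22), 0.33 (SE 0.26) and 0.04 (SE 0.18). Postn, a matrix protein of activated fibroblasts, averaged 15.4 ± 12.9 CPM against 6.11 ± 2.47 CPM, with an adjusted p of 0.304, and its log2 fold change went from 1.35 to 0.59 without NX library 3. Without NX library 1, Lox and Lyz2 passed (adjusted p = 0.0412 and 0.0248).

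None of the 30 lists passed in this comparison. Fibrillar collagens (median log2 fold change 0.36, 27 members), interferon-stimulated genes (0.32, 33 members) and cell cycle genes (0.28, 26 members) shared the smallest adjusted p of 0.0501, or 0.919 with an estimated correlation, and 0 of their members were called over all genes or adjusted over the list alone. Clock genes had a median of -0.48 over 19 members, with 0 called over all genes and 2 higher and 4 lower adjusted over the list alone (adjusted p = 0.478). The count of 0 is that of edgeR, with 2662 genes at an unadjusted p below 0.05 and a smallest adjusted p of 0.07; DESeq2 called 349, limma voom with quality weights 2270, and the authors 91 in their deposited table. Leaving out NX library 1 gave 538 calls and leaving out NX library 4 gave 34.

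AVF+NX hearts were next set against sham hearts. The natriuretic peptide genes rose: Nppa averaged 404 ± 337 CPM (SD, n = 4) against 81.9 ± 19.2 CPM (n = 3), a 4.93-fold difference (log2 2.30, SE 0.68, adjusted p = 0.0279). Without AVF+NX library 1 the log2 fold change of Nppa was 1.56, and its call ended without Sham library 1, 2 or 3 (adjusted p = 0.0851, 0.0896 and 0.064) and without a count filter (0.0557). Nppb rose 3.13-fold (log2 1.64, SE 0.37, adjusted p = 0.00826). Nppa lies on chromosome 5 from 164808323 to 164809705 on the plus strand. The stretch-responsive Ankrd1 and Rcan1, a target of calcineurin signalling, rose 1.86-fold and 1.84-fold (adjusted p = 0.0149 and 0.0108). Myh7 and Myh6 did not pass, at log2 -0.34 (SE 0.28) and -0.24 (SE 0.13). Of 20 hypertrophy and fetal programme genes measured, 6 rose and 1 fell, and 6 rose and 2 fell adjusted over the list alone, with no call for the list (adjusted p = 0.326).

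**Figure D2:**
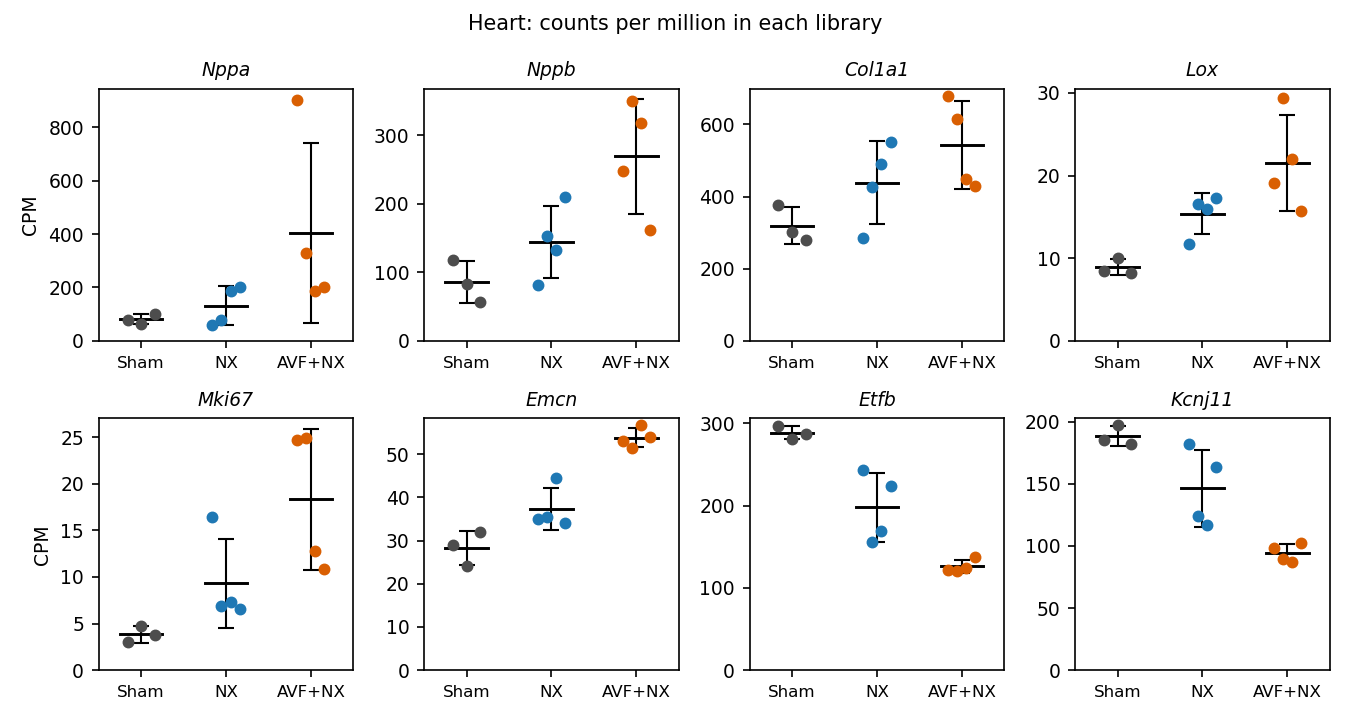
CPM (counts scaled to the library total) of 8 genes in each heart library, with 1 point per library, the mean as a line and the SD as error bars; axes start at 0. Emcn averaged 28.3, 37.3 and 53.8 CPM in the Sham, NX and AVF+NX libraries, and Etfb 288, 198 and 126 CPM.

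Matrix and fibroblast genes were higher in AVF+NX than in sham hearts. Of 27 fibrillar collagens and matrix proteins, 16 rose and none fell (18 adjusted over the list alone; median 0.82). Tenascin C (Tnc) rose 4.98-fold from 0.555 ± 0.297 CPM, fibronectin (Fn1) rose 2.12-fold, Col1a1 1.70-fold and Col3a1 1.90-fold (adjusted p = 0.0208 and 0.0211 for the collagens). Postn and Timp1 did not pass, with adjusted p values of 0.124 and 0.182. Among 21 matrix crosslinking and remodelling enzymes, 9 rose and 2 fell, with Lox at 2.44-fold and P4ha1, a collagen prolyl hydroxylase, at 2.21-fold (adjusted p = 0.00205 and 0.00183). Fibroblast markers rose in 7 of 14, including Lum and Dcn, the proteoglycans lumican and decorin, at 2.18-fold and 1.59-fold. Adjusted over the list alone, 10 enzymes and 8 fibroblast markers rose and 2 enzymes fell. The camera test called these lists at adjusted p values of 3.8e-05, 0.0231 and 0.0325, each of them adjusted p = 0.71 with an estimated correlation.

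Proliferation and interferon genes also rose after AVF+NX. Of 26 cell cycle genes, 11 rose and none fell (11 adjusted over the list alone). Mki67, which marks dividing cells, went from 3.83 ± 0.879 to 18.3 ± 7.55 CPM, and Cenpf and Kif11, which act in mitosis, rose 6.35-fold and 5.41-fold. The mitotic genes Aspm, Ckap2 and Prc1, at 6.07-fold, 6.40-fold and 5.11-fold, were among the largest rises. Of 33 interferon-stimulated genes, 21 rose and 1 fell (22 and 1 adjusted over the list alone), with the viral RNA sensor Ifih1 at 2.05-fold, Oasl2 at 2.98-fold and Oas2 at 6.86-fold. The log2 fold change of Oas2, 2.78 with all libraries, was 3.63 without Sham library 2, and its call ended without Sham library 1 or 3 (2.69 and 2.29, adjusted p = 0.072 and 0.0737). Adjusted p values were 0.00199 for the cell cycle list and 2.14e-05 for the interferon list, and adjusted p = 0.71 with an estimated correlation for both.

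Some endothelial and macrophage markers were called as well. Of 12 endothelial markers, 5 rose, such as Emcn at 1.90-fold (SE of log2 0.12, adjusted p = 0.00113) and Cdh5 at 1.46-fold; adjusted over the list alone, 6 rose and 1 fell, and the list itself missed the threshold at adjusted p = 0.0533. Of 18 macrophage markers, 4 rose and 1 fell (4 and 1 adjusted over the list alone; list adjusted p = 0.298). Lyz2 rose 2.65-fold, whereas C1qa, a complement component made by macrophages, fell from 27.9 ± 2.42 to 10.3 ± 2.22 CPM (adjusted p = 0.0353). The C1qa call held without AVF+NX library 4 and ended without any other library in turn (adjusted p from 0.0568 to 0.0867), and with the small RNA index as a covariate the log2 fold change was 0.16 (adjusted p = 0.855).

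Genes of energy metabolism and cardiac excitation were among those that fell. Of 31 fatty acid oxidation genes, 11 fell and 3 rose, both over all genes and adjusted over the list alone. Etfb, an electron carrier for that pathway, fell from 288 ± 8.07 to 126 ± 7.63 CPM (log2 -1.20, SE 0.13, adjusted p = 0.00072), and Eci1 and Acadm fell too (log2 -0.76 and -0.63). Of 34 nuclear-coded oxidative phosphorylation genes, 13 fell and 4 rose (15 and 4 adjusted over the list alone), among them Ndufv1 of complex I at -0.84 and Cox4i1 of cytochrome oxidase at -0.55. The ion channel genes Kcnj11, Kcnh2 and Scn4b fell, with log2 fold changes of -0.99, -0.96 and -0.97, among 8 falls and 2 rises in 23 genes of that list (9 and 3 adjusted over the list alone). The troponin genes Tnnc1 and Tnni3 were at -0.50 and -0.59, among 7 falls and 2 rises in 21 contractile genes (7 and 2 adjusted over the list alone). As wholes these 4 lists did not pass, at adjusted p values of 0.182, 0.1, 0.244 and 0.539. Clock genes changed as well, with Arntl (log2 3.07, SE 0.92) and Clock (0.58) higher and the clock-controlled transcription factors Tef (-0.88) and Bhlhe41 (-1.39) lower. The AVF+NX and sham values of Arntl overlapped, its log2 fold change was 4.21 without Sham library 1, and its call ended without AVF+NX library 1 or 2 or Sham library 2 or 3 (adjusted p from 0.0598 to 0.0963). In all 2 rose and 5 fell out of 19, over all genes and adjusted over the list alone, with no call for the list (adjusted p = 0.315).

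The largest falls were in short structured RNAs and genes at low counts. RF00017, RF00092, RF01268 and RF00019, which are named after families of small structured RNA, fell, with log2 fold changes of -3.42, -3.86, -3.04 and -3.04. RF01268 went from 111 ± 31.8 to 13.7 ± 3.16 CPM. Gm23880, Srm and Trnp1 were at -5.49, -5.33 and -3.45, from sham means of at most 4.8 CPM. An index over 64 such RNA genes stood at 0.57 to 0.73 in the Sham libraries, at 0.77 and 0.47 in NX libraries 1 and 4, at -0.69 and -0.52 in NX libraries 2 and 3 and at -0.69 to -0.25 in the AVF+NX libraries. The first principal component of the heart libraries, with 48.3% of the variance, parted them the same way.

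**Figure D3:**
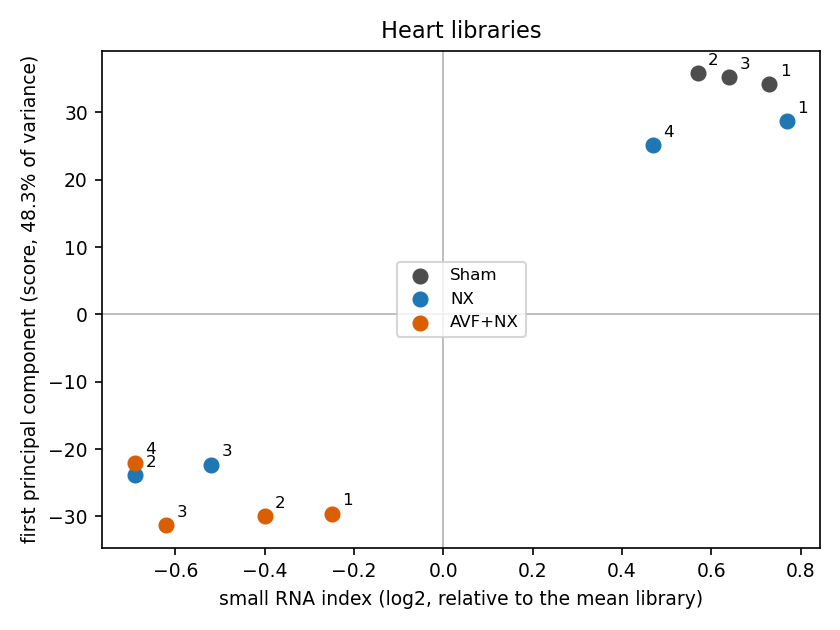
Score of each heart library on the first principal component (48.3% of the variance) against its small RNA index in log2 units, with replicate numbers beside the points. Sham and NX libraries 1 and 4 lie at index values of 0.47 or more, and AVF+NX and NX libraries 2 and 3 at -0.25 or less.

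In all, 4357 of 12794 heart genes differed between AVF+NX and Sham, 1975 higher and 2382 lower, and 806 of them changed at least 2-fold; the authors' deposited table called 5360. With the small RNA index as a covariate 23 genes were called, with log2 total count 2 and with the clock index 112. Eci1, Etfb, Mki67, Cenpf, Aspm and Prc1 were the 6 of 48 called genes taken by the naming rule that kept their call with the small RNA index. All 5 called lists kept theirs with that index or log2 total count, 2 (fibrillar collagens and interferon-stimulated genes) with the clock index, and 3 (these and cell cycle genes) in a fit of only the 2 groups. Without each library in turn 35 of the 48 genes kept their call, and Nppa, Ankrd1, Col1a1, Col3a1, C1qa, Prc1, Oas2, Arntl, Tef, Bhlhe41, RF00092 and RF00019 were among those that did not. Leaving out Sham library 1, 3 or 2 gave 2724, 2794 or 2803 calls, and leaving out AVF+NX library 1 gave 3 called lists.

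The last heart comparison, AVF+NX against NX, concerns the fistula added to nephrectomy. Adamtsl2, a matrix protein that binds fibrillin, rose 2.59-fold from 6.79 ± 1.16 to 17.4 ± 3.58 CPM (log2 1.37, SE 0.17, adjusted p = 0.0253). Mest and Emp1 rose 2.75-fold and 2.14-fold (adjusted p = 0.0378 each), Islr 2.10-fold, and F13a1 and Lyve1, both found in resident macrophages, 1.80-fold and 1.78-fold. Sparc, a collagen-binding protein, rose 1.38-fold, the antigen-presenting RT1-Da 1.70-fold and the interferon-inducible Sp100 1.82-fold. Efnb3 fell from 145 ± 33.2 to 77.3 ± 8.01 CPM, and the mitochondrial genes Etfb, Eci1, Acadm, Acadvl and Mief2 fell, with log2 fold changes of -0.65, -0.50, -0.47, -0.42 and -0.86. Nppa (log2 1.62, SE 0.59, adjusted p = 0.166), Nppb (0.90, SE 0.32, adjusted p = 0.156), Col1a1 (0.31, SE 0.20) and Col3a1 (0.59, SE 0.24) did not pass, nor did Myh6, Myh7, Postn and Timp1, at -0.30, -0.27, 0.18 and 0.26. Without AVF+NX library 1 Nppa was at 0.86, and without NX library 3 Postn was at 0.93.

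Camera called 12 of 30 lists, 9 higher and 3 lower, in AVF+NX vs NX hearts. Higher lists included fibrillar collagens (median 0.46; 1 member called over all genes and 10 adjusted over the list alone; adjusted p = 7.59e-06), interferon-stimulated genes (0.53; 0 and 7; 4.02e-06), fibroblast markers (0.26; 0 and 5; 0.00276), macrophage markers (0.33; 0 and 4; 0.00265) and cell cycle genes (0.51; 0 and 2; 0.00265). Lower lists were fatty acid oxidation (-0.10; 4 and 8 lower; 0.00276), oxidative phosphorylation (-0.11; 0 and 8 lower; 0.0188) and contractile genes (-0.06; 0 and 2 lower; 0.0272). With an estimated correlation all of these had adjusted p = 0.49 except oxidative phosphorylation with adjusted p = 0.51. With log2 total count as a covariate 8 of the 12 lists kept their call, and oxidative phosphorylation and contractile genes were among those that lost it. Gene calls numbered 43 of 12794, 22 higher and 21 lower, against 451 in the authors' deposited table.

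No gene was called between these heart groups when the fit held only their libraries (2368 genes at an unadjusted p below 0.05), with limma voom (2008 genes) or with log2 total count as a covariate (1175 genes), whereas DESeq2 called 843 (313 higher and 530 lower), edgeR without a count filter 124 and with the length trend removed 89. The edgeR count was 0 without AVF+NX library 1, AVF+NX library 2 or NX library 1 (2118, 2181 and 1940 genes at an unadjusted p below 0.05), 2 without AVF+NX library 3, 3 without NX library 4, 525 without NX library 3 and 695 without NX library 2. Of 21 called genes of the naming rule 0 kept their call without each library in turn. Lists called fell to 5, 7 and 7 without NX library 2, AVF+NX library 1 and NX library 3.

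In kidney, NX was first compared with sham surgery, which shows the remaining tissue 4 weeks after nephrectomy. Cell division genes rose: of 29 cell cycle genes, 14 passed over all genes and 25 adjusted over the list alone, all higher. Top2a, a topoisomerase of dividing cells, went from 2.37 ± 0.586 to 14.2 ± 4.47 CPM (n = 4 each; log2 2.58, SE 0.29, adjusted p = 0.00402), Mki67 rose 3.60-fold, Cenpf 4.48-fold, and the mitotic kinase Pbk went from 0.187 to 1.91 CPM. The list had an adjusted p of 1.02e-23, and adjusted p = 0.121 with an estimated correlation.

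Antibody-producing and macrophage genes were higher after NX. The immunoglobulin heavy chain gene Igh-6 rose from 1.11 ± 0.762 to 87.2 ± 47.6 CPM, Jchain, which joins immunoglobulin chains, rose 25.2-fold and Mzb1 of plasma cells 18.7-fold (adjusted p = 0.00868, 0.0182 and 0.0297). B and plasma cell markers counted 3 of 10 higher over all genes and 9 adjusted over the list alone. Macrophage markers counted 4 of 19 and 17 adjusted over the list alone, with Gpnmb at 48.3 against 3.23 CPM, Trem2 at 4.18-fold and the mannose receptor Mrc1 at 3.26-fold. The T cell signalling gene Cd247 rose 4.38-fold, among 1 of 15 T and NK cell markers over all genes and 8 adjusted over the list alone. The 3 lists had adjusted p values of 1.79e-07, 9.66e-11 and 1.68e-05, with adjusted p = 0.31, 0.31 and 0.45 with an estimated correlation. Jchain, Mzb1 and Gpnmb were not called with limma voom. Mzb1, Gpnmb and the B and plasma cell list were not called in a fit of only the NX and Sham libraries. The immune index of NX library 3 was -1.21, beside -1.46 to -1.22 in the sham libraries and -0.01 to 0.41 in the other NX libraries.

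Collagens Col1a1 (4.56-fold, adjusted p = 0.0276), Col3a1 (4.09-fold) and Col8a1 (3.44-fold) rose, the 3 members called among 29 matrix genes, with 17 adjusted over the list alone (adjusted p = 7.63e-10; adjusted p = 0.409 with an estimated correlation). Among 23 tubular injury genes Cd44 rose 2.65-fold, the 1 call over all genes, and 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.000116; adjusted p = 0.508 with an estimated correlation). Spp1, the matrix phosphoprotein osteopontin, had a log2 fold change of 1.39 (SE 0.38, adjusted p = 0.0949), and the injury markers Havcr1 and Lcn2 had 1.81 (SE 0.82) and 1.48 (SE 1.12), with adjusted p values of 0.281 and 0.535. Spp1 passed without NX library 3 (adjusted p = 0.0449), and Lcn2 was at 0.16 without NX library 4 and 2.26 without Sham library 1. Umod, Slc34a1 and Kl were at -0.07, -0.40 and -0.13, with adjusted p values from 0.412 to 0.861. Markers of other tissues were not called but lay above sham, with medians of 1.22 for 9 urothelial and 0.67 for 8 adipocyte markers, 0 called over all genes or adjusted over the list alone (adjusted p = 0.178 and 0.158). The urothelial and adipocyte indices of NX library 1 were 1.33 and 1.5, and those of the sham libraries -2.17 to -0.59 and -1.07 to 0.08.

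The cell cycle inhibitors Cdkn1a and Cdkn2b rose 2.79-fold and 6.95-fold. Proximal tubule genes as a list were lower (median -0.31, 33 members, adjusted p = 1.31e-07; adjusted p = 0.491 with an estimated correlation), with 1 member called, the brush border enzyme Ggt1 at -0.73 (SE 0.15, adjusted p = 0.0406), and 8 lower adjusted over the list alone. Plce1, a podocyte phospholipase, fell by 0.49. Camera called the clock list lower (median -0.90, adjusted p = 0.000329, and adjusted p = 0.121 with an estimated correlation), though 5 of 19 members lay above 0. Over all genes 3 were lower, and adjusted over the list alone 4 were higher and 10 lower. Hlf, Usp2 and Per2 were at -1.20, -1.06 and -1.03. The list mixes genes from both sides of the clock index, so its direction does not show that clock genes fell as a whole. The largest falls were Armc3 at -1.78, Hif3a at -1.68, Myb at -1.48, Rbfox3 and Gprin3 at -1.43 each, Fsd1l at -1.42 and Etnppl at -1.19, and Slamf6 of lymphocytes was among the largest rises at 6.93-fold.

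In all, 187 of 14322 kidney genes passed in NX vs Sham, 123 higher and 64 lower, against 819 in the authors' deposited table, and 18 of 36 lists, 13 higher and 5 lower. No gene was called by edgeR with the clock index as a covariate (1493 genes at an unadjusted p below 0.05) and 11 lists were, DESeq2 called 821 genes and limma voom 568, and 114 changed at least 2-fold. The count was 19, 29, 583 and 52 without NX library 1, 2, 3 or 4, and 20, 23 and 20 without Sham library 2, 3 or 4. Of 33 called genes taken by the naming rule, 6 (Igh-6, Pbk, Top2a, Mki67, Cenpf and Gprin3) kept their call without each library in turn. Limma voom kept 28 of the 33 and a fit of only the NX and Sham libraries 21, and Slamf6 was called in neither. The NX and sham values of Cd44 and Usp2 overlapped.

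The kidneys of AVF+NX rats differed from sham kidneys in immune, matrix and proliferation genes. All 19 macrophage markers rose, among them the lysosomal Cd68, from 5.93 ± 0.591 to 58.0 ± 19.7 CPM (n = 4 each; log2 3.29, SE 0.30, adjusted p = 4.74e-05), and C1qa at 5.58-fold. Of 15 T and NK cell markers 14 rose, with the T cell receptor chains Cd3e and Cd3g at 13.2-fold and 11.3-fold. All 10 B and plasma cell markers rose (median 5.01, also with Ms4a1 at its bound). Jchain went from 1.4 ± 0.674 to 212 ± 75.4 CPM and Igh-6 from 1.11 ± 0.762 to 1150 ± 800 CPM. The B cell gene Ms4a1, with 0 counts in the sham libraries, was at least 88.1-fold higher against a floor of 3 counts over the group. Counts adjusted over the list alone were the same for these 3 lists. Their adjusted p values were 6.26e-15, 2.07e-11 and 6.74e-11, and adjusted p = 0.203 with an estimated correlation for each.

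**Figure D4:**
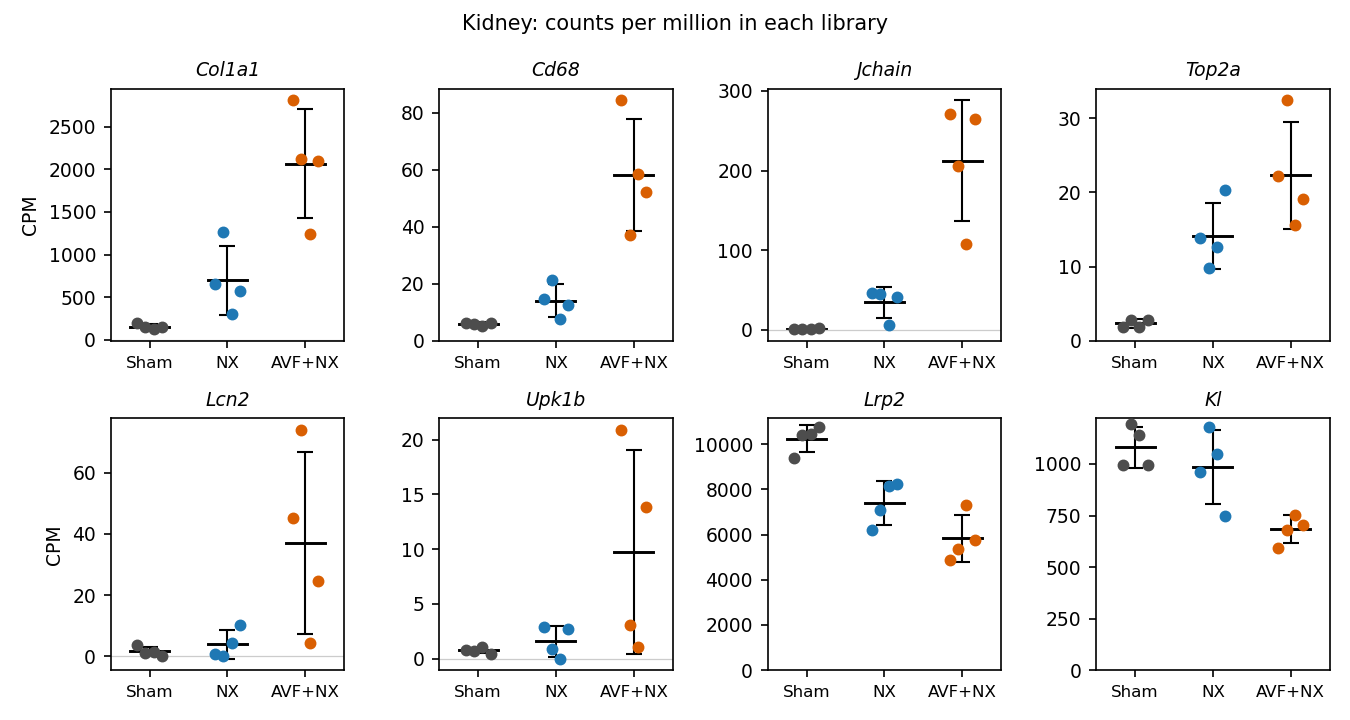
CPM (counts scaled to the library total) of 8 genes in each kidney library, with 1 point per library, the mean as a line and the SD as error bars; axes start at or just below 0. Cd68 averaged 5.93, 14.1 and 58 CPM in the Sham, NX and AVF+NX libraries, and Kl 1080, 985 and 683 CPM.

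Of 29 matrix genes, 23 rose after AVF+NX (27 adjusted over the list alone; median 1.85). Col1a1 rose 13.5-fold, from 153 ± 29.6 to 2070 ± 640 CPM, Col3a1 10.8-fold, and Postn went from 0.267 ± 0.369 to 93.4 ± 56.5 CPM. The protease inhibitor Timp1 rose 4.07-fold, and the matrix proteases Mmp7 and Mmp12 averaged 18.4 ± 11.0 and 63.9 ± 67.7 CPM against 0.0225 ± 0.045 and 0.218 ± 0.266 CPM. Of 29 cell cycle genes, 26 rose, also adjusted over the list alone, with Top2a at 9.31-fold and Mki67 at 5.94-fold. Of 33 interferon-stimulated genes, 26 rose (29 adjusted over the list alone), such as the immunoproteasome subunit Psmb9 at 2.75-fold. Adjusted p values were 1.74e-12, 1.17e-15 and 7.31e-10 for the 3 lists, with adjusted p = 0.243, 0.203 and 0.326 with an estimated correlation.

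Tubular injury genes rose in 19 of 23, with 1 lower (20 and 2 adjusted over the list alone; adjusted p = 4.66e-07; adjusted p = 0.326 with an estimated correlation). Havcr1 rose 14.7-fold to 16.9 ± 19.5 CPM, Lcn2 24.1-fold to 37.1 ± 29.7 CPM, Spp1 3.46-fold, Cd44 6.60-fold and Vim, an intermediate filament of mesenchymal cells, 3.17-fold. The log2 fold change of Havcr1 went from 3.88 to 2.67 without AVF+NX library 1, and that of Lcn2 from 4.59 to 5.36 without Sham library 1 and 4.00 without AVF+NX library 2. Without AVF+NX libraries 1 and 4 the calls of Lcn2 and Spp1 ended (adjusted p = 0.0582 and 0.1). Among the largest rises, the chemokine gene Cxcl6 and the apolipoprotein gene Apoc1, both with 0 counts in sham libraries, were at least 74.8-fold and 44.9-fold higher against the same floor.

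Proximal tubule, intercalated cell and podocyte genes were lower. Of 33 proximal tubule genes, 15 fell and none rose (22 lower adjusted over the list alone; median -0.56), including the endocytic receptors Lrp2, from 10300 ± 599 to 5840 ± 1050 CPM (log2 -0.81, SE 0.16, adjusted p = 0.00293), and Cubn at -0.74, and the phosphate transporter Slc34a1 at -0.89. Intercalated cell genes fell in 7 of 12 (8 adjusted over the list alone), with the anion exchanger Slc26a4 at -0.95. Podocyte genes fell in 8 of 16 with 1 higher (the same adjusted over the list alone), with nephrin (Nphs1) at -0.90. Adjusted p values were 8.57e-08, 0.00031 and 0.00046, with adjusted p = 0.326, 0.326 and 0.243 with an estimated correlation. Among single genes, Kl, a coreceptor for the phosphate-regulating hormone FGF23, fell (log2 -0.66), as did the vitamin D receptor Vdr (-0.64), the salt transporter Slc12a3 (-0.66) and Umod (-0.53). Principal cell genes were not called as a list (median -0.18; 3 of 12 lower over all genes and adjusted over the list alone; adjusted p = 0.106). Without AVF+NX libraries 1 and 4 the calls of Kl, Vdr, Slc12a3, Slc34a1 and Slc26a4 ended (adjusted p = 0.0598, 0.0968, 0.124, 0.199 and 0.0579), and that of Slc34a1 also without AVF+NX library 1 or Sham library 3 (0.0501 and 0.0517). The call of Umod ended without AVF+NX library 1 or 2 or Sham library 1, 2 or 4 (adjusted p from 0.0536 to 0.0861).

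**Figure D5:**
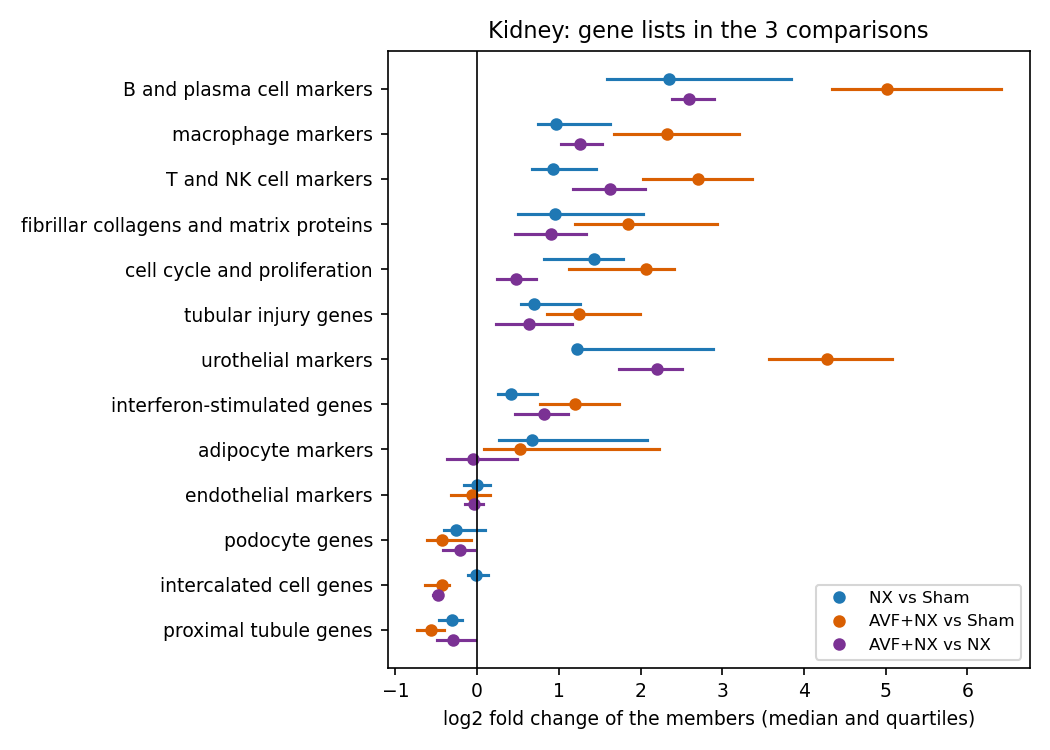
Median (point) and quartiles (line) of the log2 fold changes of the measured members of 13 gene lists in the 3 kidney comparisons. In AVF+NX vs Sham the medians were 5.01 for B and plasma cell markers, 2.32 for macrophage markers, -0.06 for endothelial markers and -0.56 for proximal tubule genes.

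Markers of other tissues were measured beside these groups. Urothelial markers, from the lining of the urinary tract, rose in 7 of 9 in AVF+NX vs Sham (8 adjusted over the list alone; median 4.28, also with Krt5 at its bound; adjusted p = 0.00152; adjusted p = 0.368 with an estimated correlation). Krt5 was at least 145-fold higher with a range from 0.404 to 26.8 CPM, and Upk1b averaged 9.75 ± 9.32 against 0.754 ± 0.245 CPM. The urothelial index was 3.46 and 3.17 in AVF+NX libraries 1 and 4, 1.22 in library 2 and -0.51 in library 3, while the immune index ran from 1.22 to 1.88 over these libraries and from -1.46 to -1.22 over the sham libraries. Endothelial markers had a median of -0.06, with 1 higher and 3 lower of 12 (1 and 5 adjusted over the list alone; adjusted p = 0.238), and adipocyte markers 0.52, with 2 higher and 1 lower of 8, over all genes and adjusted over the list alone (adjusted p = 0.303). Clock genes had 2 higher and 4 lower of 19 (2 and 7 adjusted over the list alone, list adjusted p = 0.11). Hlf and Per2 were at -0.90 and -0.81 and the clock repressor Nfil3 at 2.32. The AVF+NX and sham values of Per2 and Nfil3 overlapped, and Per2 did not keep its call without each library in turn. Hlf and Nfil3 did not keep theirs without AVF+NX libraries 1 and 4.

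The largest falls included Klk1c2 (-2.56), Olr1411 (-2.49), Cyp1a1 (-2.01), Tcf24 (-1.75), Il20ra (-1.73), Cyp2f4 (-1.66) and Rxfp2 (-1.65). Of these falls only Olr1411 and Rxfp2 kept their call without AVF+NX libraries 1 and 4. Klk1c2, Cyp1a1 and Tcf24 also did not keep it without each library in turn. The AVF+NX and sham values of Cyp1a1 and Tcf24 overlapped. In all 3594 of 14322 kidney genes passed in AVF+NX vs Sham, 2279 higher and 1315 lower, and 1388 changed at least 2-fold; the authors' deposited table called 4403. Camera called 26 of 36 lists, 18 higher and 8 lower. Without AVF+NX libraries 1 and 4 together 32 of 49 called genes of the naming rule kept their call. Calls numbered 1294 without these libraries, 2313 without library 1 alone and 992 with the clock index as a covariate.

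Kidney AVF+NX and NX were compared to see what the fistula added. Immune genes were higher again: 13 of 19 macrophage markers (15 adjusted over the list alone), 10 of 15 T and NK cell markers (14), all 10 B and plasma cell markers and 8 of 10 genes of MHC class II antigen presentation (10). Cd68 went from 14.1 ± 5.74 to 58.0 ± 19.7 CPM (n = 4 each; log2 2.05, SE 0.28, adjusted p = 0.00484), C1qa rose 2.89-fold, Cd3e 4.29-fold, Cd3g 4.63-fold, Mzb1 6.03-fold and Cd74, the invariant chain of MHC class II, 2.16-fold. Adjusted p values were 8.82e-13, 5.88e-12, 8.75e-11 and 1.22e-09 for the 4 lists, and adjusted p = 0.221 with an estimated correlation for each. The chemokine gene Cxcl9 rose 4.24-fold.

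Matrix genes Postn, Tnn and Sfrp4 rose 11.7-fold, 12.5-fold and 12.6-fold, Col1a1 rose 2.96-fold and Tgfbi 2.11-fold, and the matrix list had 4 of 29 higher (15 adjusted over the list alone; adjusted p = 1.2e-08; adjusted p = 0.324 with an estimated correlation). Igh-6, Ms4a1, Scart1 and Acod1, an itaconate-producing enzyme of macrophages, rose 13.1-fold, 13.5-fold, 13.9-fold and 8.56-fold. The log2 fold changes of Ms4a1 and Acod1 went from 3.76 and 3.10 to 5.29 and 3.88 without NX library 4, that of Sfrp4 from 3.65 to 4.37 without NX library 2, and those of Scart1 and Tnn from 3.79 and 3.65 to 3.08 without AVF+NX library 1 and 2.97 without AVF+NX library 2. Cell cycle genes had 1 of 29 higher over all genes and 5 adjusted over the list alone (median 0.47; adjusted p = 2.76e-05; adjusted p = 0.34 with an estimated correlation).

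Single genes of distal segments fell: the thiazide-sensitive transporter Slc12a3 was at -0.74, the sodium channel subunit Scnn1g at -0.60, Npnt at -0.54, the ammonia transporter Rhbg at -0.54, the calcium channel Trpv5 at -0.69, Casr at -0.54 and Kl at -0.53. Distal convoluted and connecting tubule genes had 3 of 9 lower (6 adjusted over the list alone; adjusted p = 0.000127; adjusted p = 0.318 with an estimated correlation). Thick ascending limb genes had 2 of 13 lower (6; adjusted p = 3.96e-05; adjusted p = 0.324 with an estimated correlation). Intercalated cell genes had 3 of 12 lower (9 adjusted over the list alone; adjusted p = 1.59e-06; adjusted p = 0.291 with an estimated correlation). Principal cell genes had 3 of 12 lower (5; adjusted p = 0.000164; adjusted p = 0.221 with an estimated correlation). The largest falls were Hmx3 at -1.39, Lhx1 at -0.99, Eno4 at -0.91, Capn6 at -0.89 and Dock3 at -0.83. Havcr1, Lcn2, Spp1, Umod and Slc34a1 did not pass, at log2 2.06 (SE 0.69), 3.11 (SE 0.94), 0.40 (SE 0.37), -0.46 (SE 0.16) and -0.49 (SE 0.24). Havcr1 was at 0.87 without AVF+NX library 1 and passed without AVF+NX library 3 (adjusted p = 0.0362), and Lcn2 passed without AVF+NX library 3 or NX library 4 (3.48 and 4.43, adjusted p = 0.0292 and 0.0317). Urothelial markers as a list were higher in this comparison too (median 2.20; 0 of 9 called over all genes or adjusted over the list alone; adjusted p = 0.00173; adjusted p = 0.389 with an estimated correlation).

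In this comparison 870 of 14322 genes passed, 698 higher and 172 lower, against 1123 in the authors' deposited table, and 26 of 36 lists, 17 higher and 9 lower; 411 genes changed at least 2-fold. Without AVF+NX libraries 1 and 4, 83 genes were called, 83 higher and 0 lower. The 10 of 35 called genes of the naming rule that kept their call included Cd68, Cd3g, Cd74, Cxcl9, Igh-6, Scart1, Sfrp4, Tgfbi and Tnn. C1qa, Cd3e, Mzb1, Ms4a1, Acod1, Postn and Col1a1 did not keep theirs, nor did Slc12a3, Scnn1g, Npnt, Rhbg, Trpv5, Casr and Kl. Calls numbered 267 in a fit of only the 8 libraries compared and 1487 with DESeq2. They numbered 324, 449 and 1585 without AVF+NX library 1, 4 or 3, and 384 and 576 without NX library 3 or 2. Of 35 called genes of the naming rule 23 kept their call without each library in turn. Hmx3, Lhx1, Eno4, Capn6, Dock3, Slc12a3, Scnn1g, Trpv5, Kl and Col1a1 were among those that did not. The AVF+NX and NX values of Col1a1 and Kl overlapped.

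Both operations shared their sham libraries, which raises the correlation of their fold changes with no effect at all. In kidney, 117 genes were higher and 51 lower in both NX and AVF+NX, and 0 went opposite ways. Independent lists of these sizes would share 19.6 higher and 5.88 lower genes. In 20 simulations all libraries were drawn from the sham mean, with no change in any group, and the mean overlap was 0. Such counts leave little to call, so that overlap is no baseline for the shared calls. The fold changes correlated across genes with r = 0.901 against a simulated 0.494, and their covariance was 0.546 against 0.0403; genes are not independent replicates. With the sham libraries split between the comparisons the overlap was 0, since NX then had 0 calls against 2331 for AVF+NX; the correlation was 0.776 and the covariance 0.536. In heart the overlap was 0 (simulated mean 0.05), which the 0 calls of NX vs Sham fixed in advance. The heart correlation was r = 0.815 against a simulated 0.615, with a covariance of 0.179 against 0.0416. The 3 heart sham libraries were too few to split, so part of this excess may come from them. The simulated counts also held no structure among libraries, whereas heart NX libraries 2 and 3 lay beside AVF+NX on the first component. The excess in heart therefore does not by itself show an effect shared by the operations. Leaving out kidney Sham library 2, 3 or 4 or NX library 1, 2 or 4 took the kidney overlap to 18, 21, 19, 19, 28 or 42 and leaving out NX library 3 to 525; leaving out heart NX library 1 or 4 took the heart overlap to 493 or 32.

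The same operation was also compared between the organs, with a test of the heart effect minus the kidney effect over 15222 genes. For AVF+NX vs Sham 4248 genes differed, 2021 with the higher effect in heart and 2227 in kidney. The estimates of 3163 of them had opposite signs, whether or not either effect passed by itself. Pla2g7, a lipoprotein-associated phospholipase of macrophages, had in this fit an effect of -0.65 in heart and 3.39 in kidney (difference -4.04, SE 0.35, adjusted p = 1.24e-06). The uncoupling protein gene Ucp2 had effects of -0.39 and 1.61. The endothelial gene Emcn had 1.01 in heart and -0.31 in kidney (difference 1.32, SE 0.16). Adding the fistula (AVF+NX vs NX) gave 170 differing genes, 38 higher and 132 lower in heart, with Pla2g7, the T cell factor Tcf7 and the neutrophil oxidase subunit Ncf1 at differences of -2.17, -2.19 and -2. Nephrectomy alone gave 24, 12 each way, with Plxna2, a receptor for semaphorins, at 0.85 (SE 0.15) and Ubtd1 at -1.08 (SE 0.17). The small RNA index parted AVF+NX from Sham hearts, and calls in that heart comparison went from 4357 to 23 with it as a covariate. The organ differences were not tested with that covariate.

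Scaling moved the balance of the organ differences, with 22 higher and 14 lower for NX vs Sham, 2391 higher and 2049 lower for AVF+NX vs Sham and 60 higher and 119 lower for AVF+NX vs NX under RLE. DESeq2 called 480 (331 higher and 149 lower) for NX vs Sham and 657 (265 higher and 392 lower) for AVF+NX vs NX, and the count for AVF+NX vs NX was 112 without a filter. The NX vs Sham count was 452, 325 and 101 without heart NX library 1, heart NX library 4 or kidney NX library 3. It was 2 and 7 without kidney Sham library 1 or 3, and 0 without heart NX library 2 or 3, any heart Sham library, kidney NX library 1 or 2 or kidney Sham library 2 or 4 (1833 to 2262 genes at an unadjusted p below 0.05 in edgeR). The AVF+NX vs NX count was 703, 536, 59 and 95 without heart NX library 2, 3, 4 or 1, 68, 76 and 62 without heart AVF+NX library 1, 2 or 3, 50 and 99 without kidney AVF+NX library 1 or 4, and 72 and 315 without kidney NX library 3 or 4.

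None of the lists called in any comparison kept its call with an estimated correlation between genes. In several lists that were not called the median, mean and test differed in sign. In heart AVF+NX vs Sham these included the glycolysis, NRF2 and p53 lists and atrial, red cell and T and NK cell markers. In kidney NX vs Sham they included MHC class II and phosphate, calcium and vitamin D genes. In kidney AVF+NX vs Sham they included NRF2 genes, with a median of -0.07, a mean of 0.45 and an upward test (adjusted p = 0.658). In the fistula comparisons they included NRF2 genes in both organs and glycolysis and ion channel genes in heart.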

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

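The tests of the heart libraries, of clock genes across the organs, of tubule share and of fat were chosen after the result was seen. Among 416 combinations of a gene and a group of 4 libraries, 29 held a library standing apart, as did 2 of 25 combinations of a library measure and a group. A library stands apart where its gap to the nearest other, divided by the range of the group, exceeds the 95% critical value of Dixon's test, which chance alone gives in about 5% of groups, or 1 in 20.

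Kidney NX library 3 was the lowest of its group for 6 immune, injury or stress genes. It held 18.2 CPM of Igh-6 against 94.1 to 123 in the others (0.861), 5.76 of Jchain against 41.6 to 46.5 (0.946), 0.565 of Mzb1 against 4.19 to 5.04 (0.909) and 0.904 of Cd3g against 3.21 to 3.33 (0.97). Slc7a11, a cystine transporter, was at 0.226 against 2.58 to 3.55 CPM (0.864) and Vim at 101 against 182 to 194 CPM (0.9). Kidney NX library 4 had the highest depth, 18782085 counts against 9360065 to 9458673 (0.989), and the lowest mitochondrial share, 4.15% against 9.37% to 9.63% (0.953). In that library Myb (0.891), Umod (0.882) and Cyp51 (0.863) were highest, at 2.08, 3880 and 43.2 CPM, and Il20ra (0.841) and Scnn1g (0.881) lowest, at 1.33 and 52.5 CPM.

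The other kidney libraries stood apart for at most 3 genes each. Armc3 and Pdia4 were highest in NX library 1, at 20.3 and 124 CPM (0.835 and 0.909), and Hmox1 in NX library 2 at 35.1 CPM (0.834). Gpnmb was lowest in AVF+NX library 2, at 129 against 328 to 387 CPM (0.849). Mmp7 was lowest in AVF+NX library 3, at 2.42 against 19.7 to 25.9 CPM (0.882), and Lhx1 highest there at 15.8 CPM (0.87). In Sham library 4 Hif3a was highest at 5.48 CPM (0.856) and Hmox1 lowest at 4.94 CPM (0.832). Capn6 was lowest in Sham library 1 at 4.12 CPM (0.8291). Mmp7 in Sham library 4 and Acod1 in Sham library 2 had a ratio of 1 because the other sham libraries were at 0, with 0.0899 and 0.247 CPM.

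In heart, Emcn was highest in NX library 3 at 44.5 against 34.1 to 35.5 CPM (0.844), and Mki67 in NX library 1 at 16.5 against 6.54 to 7.36 CPM (0.873). Oasl2 was highest in AVF+NX library 1 at 17.7 CPM (0.883), and P4ha1 lowest in AVF+NX library 4 at 56.9 against 80.2 to 81.8 CPM (0.945). Clock was lowest in AVF+NX library 4 and in NX library 4, at 76.0 and 74.2 CPM (0.839 and 0.845), and Tef highest in NX library 4 at 130 CPM (0.8294).

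Effects of the same operation differed between heart and kidney in 24 genes for NX vs Sham, 4248 for AVF+NX vs Sham and 170 for AVF+NX vs NX by a test of the difference in edgeR. That test held no covariate for the small RNA index, which parted AVF+NX from Sham hearts. For NX vs Sham the heart effect exceeded that in kidney for Plxna2 (0.85), Plce1 (0.89), Sgms1 (0.75) and Pxk (0.95) and lay below it for Ubtd1 (-1.08), Ankrd13d (-2.76), Stard3 (-0.74), Fam78a (-1.69) and Pla2g7 (-1.87). For AVF+NX vs Sham the differences were 1.43 for Arhgef28, 1.32 for Emcn, 0.90 for Clcn6, 1.05 for Plxna2, -4.04 for Pla2g7, -2 for Ucp2, -3.21 for Agap2, -3.15 for Fam78a and -1.67 for Ubtd1. For AVF+NX vs NX they were 1.05 for Arhgef28, 1.59 for Adamtsl2, 0.98 for Smpx, 1.19 for Syt17, 0.95 for Aif1l, -2.17 for Pla2g7, -2.19 for Tcf7, -2 for Ncf1, -2.40 for Cdnf and -2.30 for Tbc1d10c.

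Other splits of the same samples were counted for every count of calls, with all 35 splits within an organ and 80 drawn for the organ differences, the real one included. For genes, no other split gave as many as the real one in heart AVF+NX vs Sham (1 of 35 splits, real 4357, highest other 1247), heart AVF+NX vs NX (1 of 35, real 43, highest other 10), kidney NX vs Sham (1 of 35, real 187, highest other 14), kidney AVF+NX vs Sham (1 of 35, real 3594, highest other 0) and kidney AVF+NX vs NX (1 of 35, real 870, highest other 86). Chance is then unlikely but not excluded, since 1 of 35 is the smallest share possible and no adjustment was made over the counts. For the organ differences, no other split drawn gave as many for AVF+NX vs Sham (1 of 80, real 4248, highest other 1241) or AVF+NX vs NX (1 of 80, real 170, highest other 132). For NX vs Sham 2 of 80 splits gave as many, and another split called 76 genes against the real 24, so chance is not excluded. In heart NX vs Sham 35 of 35 splits gave at least the real 0, and the split that put NX library 1 with the sham libraries called 1172 genes, which points to a structure of the samples. The numbers of lists were exceeded by other splits, and chance cannot be excluded for them either. In heart 35 of 35 splits gave as many for NX vs Sham (real 0, highest other 9), 14 of 35 for AVF+NX vs Sham (real 5, highest other 11) and 6 of 35 for AVF+NX vs NX (real 12, highest other 15). In kidney 6 of 35 did for NX vs Sham (real 18, highest other 26), 2 of 35 for AVF+NX vs Sham (real 26, highest other 27) and 3 of 35 for AVF+NX vs NX (real 26, highest other 27).

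The heart libraries part into 2 sets on the first component, with NX libraries 2 and 3 beside AVF+NX. The gap between the sets, 47.1 against a widest range of 10.6 inside them, was 43.7 after thinning to equal depth and 44.8 after removing the gene length trend, which argues against the number of reads or gene length as the whole cause. The small RNA index had a gap of 0.99 inside NX, against ranges of 0.44 in AVF+NX and 0.16 in Sham, so library batches that differ in small structured RNA may take part. In AVF+NX vs Sham 23 of 12794 genes were called with that index as a covariate and 2 with log2 total count, since the median absolute log2 change of the 4357 called without them went from 0.60 (median SE 0.15) to 0.30 (SE 0.18) and 0.40 (SE 0.19), with 96% and 100% keeping their sign, and both measures differ between the groups. Tested beside the groups, the index itself was called in 2262 genes and log2 total count in 1. The fall to 2 calls with log2 total count does not by itself show an effect of depth. Batches that go with total count and an effect of surgery stay open as well, and the labels give no batch.

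Single clock genes differed from sham in heart after AVF+NX and in kidney after both operations, and in heart after NX 0 of 19 were called. The clock index nevertheless ran from -0.75 to 1.8 in NX hearts and from -2.21 to -1 in sham hearts. The NX vs Sham changes of heart and kidney had the same sign in 17 of 19 genes. They correlated with r = 0.92 (permutation p = 1e-05, rho = 0.932, r = 0.854 without Arntl and Npas2). Across 19 clock genes the AVF+NX vs Sham changes of heart and kidney correlated with r = 0.864 (permutation p = 1e-05, the smallest that 100000 permutations can give, and adjusted p = 1e-05; rho = 0.842, permutation p = 5e-05; r = 0.774 without Arntl and Npas2), though genes are not independent replicates. Within groups the clock index of same-numbered hearts and kidneys correlated with r = 0.961 over 11 pairs (exact two-sided permutation p = 0.00116; rho = 0.955, exact p = 0.00434; r = 0.936 without the 2 farthest pairs), in a family of 3 relations. These correlations may reflect a time of day at collection that differed from animal to animal and between groups. The one within groups may also reflect same-numbered organs from 1 animal. An effect of surgery on the clock stays open, since the labels give no collection time.

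Immune and matrix genes were higher in AVF+NX kidneys. A lower share of tubule cells would raise every other cell type, but the upper quartile of endothelial changes was 0.16 against a lower quartile of 1.67 for macrophage markers in AVF+NX vs Sham. For urothelium carried along, the lowest AVF+NX library's immune index lay 2.44 above the highest sham library's, but that gap does not measure urothelium. The urothelial index ran from -0.51 to 3.46 in the AVF+NX libraries and from -2.17 to -0.59 in the sham libraries. AVF+NX library 3, the lowest at -0.51, had an immune index of 1.63. Since every AVF+NX library lay above sham in both indices, urothelium stays open as a part. For fat, the upper quartile of adipocyte changes in AVF+NX vs NX was 0.49 against a lower quartile of 1.03 for macrophage markers, while in AVF+NX vs Sham it was 2.23 against 1.67 and leaves fat open as a part. A response of the kidney to the operations may also underlie the difference, as a hypothesis found on these same data.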

How the results depend on the processing

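The covariates, thinning, length trend and fits without 2 kidney libraries were chosen after seeing the data, and the other alternatives were fixed in advance. Of the values of named genes under alternatives fixed in advance, 3011 kept their direction and side of the threshold, 612 lost the call and 22 gained it; under added ones 421, 265 and 2 did so and 2 reversed. For list tests the counts were 2455, 190 and 64 under those and 474, 32 and 32 under added ones, with 2 reversed. With the small RNA index as a covariate, C1qa and RF00019 in heart AVF+NX vs Sham went to 0.16 and 0.05. With the clock index as a covariate, the kidney NX vs Sham tests of fibroblast markers (adjusted p = 0.956, downward) and fatty acid oxidation (adjusted p = 0.0629, upward) turned. Where a setting changed a result below, the cause was not tested, except that a fold threshold leaves less to call.

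A fold threshold of 2 left 806 and 8 calls in heart AVF+NX vs Sham and vs NX, and 114, 1388 and 411 in kidney NX vs Sham, AVF+NX vs Sham and AVF+NX vs NX. Without a count filter heart NX vs Sham had 4 genes and 3 lists, heart AVF+NX vs NX 124 genes, the organ difference of AVF+NX vs NX 112 and the heart overlap 4. DESeq2 called 349 and 843 in heart NX vs Sham and AVF+NX vs NX, 821 and 1487 in kidney NX vs Sham and AVF+NX vs NX, and 480 and 657 in the organ differences of NX vs Sham and AVF+NX vs NX, with overlaps of 319 in heart and 689 in kidney. Limma voom with quality weights called 2270 in heart NX vs Sham, 0 in heart AVF+NX vs NX (2008 at an unadjusted p below 0.05) and 568 in kidney NX vs Sham. Fits of only the groups compared gave 0 genes in heart AVF+NX vs NX (2368 at an unadjusted p below 0.05), 267 in kidney AVF+NX vs NX, and 2 and 3 lists in heart NX vs Sham and AVF+NX vs Sham. With an estimated correlation 0 lists were called in each comparison by camera, where 5 and 12 in heart and 18, 26 and 26 in kidney had been. Of those, fry called 0 and 0 in heart AVF+NX vs Sham and vs NX, 6 in kidney NX vs Sham, 22 in kidney AVF+NX vs Sham and 14 in kidney AVF+NX vs NX. With the sham libraries split, the kidney overlap was 0.

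The small RNA index as a covariate gave 23 genes and 14 lists in heart AVF+NX vs Sham and 6 lists in heart NX vs Sham. Log2 total count as a covariate gave 2 genes in heart NX vs Sham, 2 genes and 9 lists in heart AVF+NX vs Sham and 0 genes in heart AVF+NX vs NX (1175 at an unadjusted p below 0.05). The clock index as a covariate gave 112 genes and 3 lists in heart AVF+NX vs Sham, 0 genes (1493 at an unadjusted p below 0.05) and 11 lists in kidney NX vs Sham, and 992 genes in kidney AVF+NX vs Sham. Removing the length trend gave 89 genes in heart AVF+NX vs NX. Without kidney AVF+NX libraries 1 and 4, 1294 genes were called against Sham and 83 against NX.

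The fit with a replicate block called 61 genes and 1 list in heart NX vs Sham, 669 genes in kidney NX vs Sham, 1647 in kidney AVF+NX vs NX, and 119 and 268 in the organ differences of NX vs Sham and AVF+NX vs NX. Neither kind of same-numbered pair had every correlation above 0.1, so no pairing was taken as shown. Libraries with the same number in other groups correlated with r from -0.116 to 0.124 in heart, above 0.1 in 1 of 10 pairs, and from -0.0748 to 0.382 in kidney, above 0.1 in 7 of 12. Hearts and kidneys with the same group and number had r from -0.0271 to 0.277, above 0.1 in 5 of 11 (median 0.0946). Hearts and kidneys of a group with other numbers had 0 of 30 above 0.1 (median -0.048, highest 0.0823). Of 11 hearts 8 correlated best with the kidney of their own number, 3 of 3 after sham surgery, 1 of 4 after NX and 4 of 4 after AVF+NX, a hint from the data and not from the design. Whether same-numbered organs come from 1 animal stays open, and the test of organ differences treats the libraries as independent.

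Leaving out each library in turn gave 0 to 538 genes and 0 to 3 lists in heart NX vs Sham, 2724 to 4236 genes and 3 to 6 lists in heart AVF+NX vs Sham, and 0 to 695 genes and 5 to 14 lists in heart AVF+NX vs NX. It gave 19 to 583 genes in kidney NX vs Sham, 2313 to 4428 in kidney AVF+NX vs Sham and 324 to 1585 in kidney AVF+NX vs NX. The organ differences ranged from 0 to 452 for NX vs Sham and from 50 to 703 for AVF+NX vs NX, and the overlaps from 0 to 493 in heart and from 18 to 525 in kidney. Lists in heart NX vs Sham numbered 2 without NX library 1, NX library 3 or Sham library 1 and 3 without NX library 2. Of the called genes of the naming rule, 35 of 48 and 0 of 21 in heart AVF+NX vs Sham and vs NX and 6 of 33, 41 of 49 and 23 of 35 in kidney NX vs Sham, AVF+NX vs Sham and AVF+NX vs NX kept their call without each library in turn. Simulated AVF+NX vs Sham counts recovered 22.4% of genes changed 1.5-fold in heart and 41.8% in kidney. Depth was varied alone only by thinning the heart libraries to equal depth, which gave 3920 calls against 4357 in AVF+NX vs Sham.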

Other observations

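The observations on single lists below were picked after the values were seen. Some genes of the unfolded protein response were higher in AVF+NX than in NX kidneys. Neither Pdia4 nor Creld2 kept its call without AVF+NX libraries 1 and 4. Pdia4, which forms disulfide bonds in new proteins, rose 1.48-fold from 107 ± 11.8 to 158 ± 13.7 CPM (SD, n = 4 each; adjusted p = 0.0062 in edgeR), and Creld2 rose 1.63-fold. Of 20 unfolded protein response genes 4 rose and 1 fell, or 7 and 2 adjusted over the list alone (adjusted p = 0.00114; adjusted p = 0.291 with an estimated correlation). All 10 B and plasma cell markers were higher in the same comparison (median 2.60), and whether the rise lies in such secretory cells was not tested. Against Sham the same list was lower in NX (median -0.17; 0 called over all genes or adjusted over the list alone; adjusted p = 0.0138; adjusted p = 0.45 with an estimated correlation) and not called in AVF+NX (median 0.12; adjusted p = 0.279). In AVF+NX vs Sham kidneys 7 of 20 cholesterol synthesis genes rose, or 9 with 1 lower adjusted over the list alone (adjusted p = 0.00197; adjusted p = 0.326 with an estimated correlation), with Cyp51 at 1.80-fold.

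Several single stress genes were higher in kidney after the operations. Hmox1, which breaks down heme, rose 3.05-fold after NX and 4.84-fold after AVF+NX against Sham (adjusted p = 0.0226 and 0.000141), Slc7a11 rose 18.6-fold after NX, and Cdkn1a rose 4.34-fold after AVF+NX. The NX and sham values of Slc7a11 overlapped, with NX library 3 at 0.226 CPM. Its call ended with limma voom and in a fit of only the 2 groups. The p53 and senescence list was higher in NX vs Sham (2 of 12 over all genes, 5 adjusted over the list alone; adjusted p = 0.00948; adjusted p = 0.169 with an estimated correlation) and in AVF+NX vs Sham (5 higher and 2 lower, 6 and 2 adjusted over the list alone; adjusted p = 0.0215; adjusted p = 0.203 with an estimated correlation). The NRF2 and oxidative stress list was not called in NX vs Sham (2 of 20 higher; adjusted p = 0.1) or AVF+NX vs Sham (6 higher and 1 lower; median -0.07; adjusted p = 0.658). In heart AVF+NX vs Sham 4 of 23 immediate-early genes fell, over all genes and adjusted over the list alone, with no call for the list (adjusted p = 0.238).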
